A study of Escherichia coli with 13 samples.

How the data were processed

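RNA levels were measured by sequencing in cultures of Escherichia coli CSH50, a K-12 laboratory strain, grown with aeration in rich LB medium at constant temperature and pH. The 13 libraries came from 3 genotypes given in the labels: wild type (5 libraries, at 60, 120, 180, 300 and 420 min), a fis mutant and an hns mutant (4 libraries each, at 60, 120, 180 and 420 min). Each genotype and time had 1 library, so there was no replicate spread and no p-value was computed.

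The authors deposited 1 table of normalised signal per genotype, each with 4582 genes and a column for every 10 min from 0 to 420 min. Each deposited column summed to 1, so the values were shares of all signal in genes per unit of gene length, printed here multiplied by 1e+06 (ppm). The aligner, the genome build, the counting tool, the use of strand and the treatment of reads with several matches are not given in the sources used here. The genotype of each table was taken from the match between its name and the sample titles. Columns at unsampled minutes were interpolated: they held values below 0, and the column for 0 min equalled that for 420 min. Only the columns at the sampled minutes, which held no value below 0, entered the comparisons. No value was given for 42 genes in each table, which left 4540.

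Read depth was recovered from the deposited signal. The product of value and gene length came in whole multiples of a step worth 1 base of coverage, with 51 such steps taken as 1 read. Between 92.8% and 95.9% of the low values in each library were whole within a tolerance of 0.1 bases. Read counts are this coverage divided by the read length, so they need not be whole and are printed rounded. With a read of 50 or 52 bases the share was at most 56.2%. Between 24.6% and 37.9% of values were whole in the interpolated columns examined. The recovered totals ran from 1.72 M reads in genes (hns mutant, 420 min) to 4.64 M (hns mutant, 60 min), 1 M being 1e+06 reads. A count of 0 in a gene of 1 kb allowed a level of up to 0.536 ppm in the deepest library and 2.11 ppm in the shallowest, taking 3 reads as the floor per library. Intervals are exact 95% intervals for a ratio of read counts. Intervals and floors cover counting error only, and reads copied by PCR are not independent molecules.

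Values were compared as log2(ppm + 0.840), the pseudocount being the 5th percentile of all values above 0. Log2 differences on this scale understate the difference of genes of low level. Folds printed for single genes are instead ratios of ppm without the pseudocount, or of ppm to the floor where given as at least. At few reads such folds are larger than on the log2 scale and uncertain. The 20% of genes with the lowest mean level over all libraries (below 2.95 ppm) were left out, and 3632 genes remained. The filter left out 26 of 52 flagellar genes, 9 of 31 H-NS silenced loci, all 6 lac-pro genes and at most 4 members of any other list. The genes kept had a median of 85.3 reads per library, and those in their decile of lowest level 11.4 reads. Wild type was compared between 420 and 60 min. Each mutant was compared with wild type at the 4 shared times, and a gene was listed when it was at least 2-fold higher, or at least 2-fold lower, at all 4. These rules, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

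For each comparison the genes named were the targeted genes, the 10 listed genes with the largest positive and the 10 with the largest negative log2 difference that had a gene name, and the 2 highest and 2 lowest members of each list. Other genes are said to be named after their values were seen. There were 24 lists, covering nucleoid-associated proteins, topoisomerases, sigma factors, ribosomal proteins, translation factors, flagella, stationary phase, acid resistance, H-NS silenced loci, the O-antigen cluster, central and energy metabolism, uptake, biosynthesis, stress responses, ribosomal RNA and the lac-pro region. A list's median was placed as a percentile among 10000 random lists of the same size matched on mean level in 20 bins. Percentiles describe these libraries and are not tests. Where the median of all genes differed between libraries, list medians were also expressed relative to it. Gene names came from the reference table of assembly ASM584v2 (strain MG1655), to which 4387 of the 4582 gene names matched, 4031 by symbol and 356 by synonym. Gene order was the row order of the deposited tables, with the replication origin placed at the gene mioC. No coordinates are printed, since the build of the deposited tables is unknown. Without strand, reads from a gene and an antisense partner could not be told apart. Near-identical copies (gadA and gadB, tufA and tufB, the ribosomal RNA genes and many transfer RNA genes) and genes that overlap are uncertain, since the handling of shared reads is unknown.

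The listing rule was tested on simulated counts drawn for 3553 genes from the measured levels and depths, with 50 genes changed at each size. In the simulated fis comparison 0 of 50 genes changed 2-fold, which is the threshold itself, and 44 of 50 genes changed 4-fold (88%) were listed. In the simulated hns comparison 2 of 50 genes changed 2-fold (4%), 34 of 50 changed 4-fold (68%) and 44 of 50 changed 8-fold (88%) were listed. In that draw none of 3353 unchanged genes was listed in either, and 0 genes were listed in the wrong direction. In 100 further draws of unchanged mutants over 3553 genes at most 3 genes were listed in the fis comparison and at most 1 in the hns comparison. These draws carry counting noise only and say nothing about differences between cultures. Each simulated change was the same at all 4 times, and no offset between libraries was simulated. Folds between 2 and 4 were not simulated. Alternatives covered the pseudocount, the filter, the scaling between libraries (median-of-ratios size factors and upper quartile), the fold threshold, the interpolated neighbouring columns, the times compared and, chosen after the data were seen, a minimum of 20 reads and other treatments of the fis-labelled library at 420 min. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.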

Results

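Total RNA of E. coli CSH50 was sequenced along a batch culture, from 60 to 420 min after the start, in wild type, in a fis mutant and in an hns mutant. Fis and H-NS are abundant DNA-binding proteins that shape the bacterial chromosome; Fis is best known as a growth phase regulator and H-NS as a silencer of many genes. Every genotype and time was represented by 1 library, so no value below has a replicate error, and each difference compares libraries rather than conditions. Wild-type depth was 3.24, 3.45, 3.71, 2.78 and 1.93 M reads in genes at 60, 120, 180, 300 and 420 min. The libraries labelled fis mutant held 3.06, 2.48, 3.69 and 2.07 M reads, and those of the hns mutant 4.64, 2.52, 2.02 and 1.72 M, at 60, 120, 180 and 420 min.

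The make-up of the signal differed strongly between early and late libraries. The most abundant transcript in all 13 was ssrA, the tmRNA that rescues stalled ribosomes (named after its values were seen), at 4.44% of signal in wild type at 60 min and 24.3% at 420 min. Stable RNAs together made up 19.97% of wild-type signal at 60 min and 68.9% at 420 min, against 51.5% at 420 min in the fis-labelled library and 59.1% in the hns mutant. The share of ribosomal RNA in wild type was 9.06% at 60 min and 35.2% at 420 min. The 10 most abundant genes took 17.1% of wild-type signal at 60 min and 69.1% at 420 min. Ribosomal protein genes held 39.4% at 60 min, more than ribosomal RNA. These are shares of signal per unit of gene length, and the treatment of reads with several matches is not given. Any removal of ribosomal RNA was not examined. The shares therefore describe the libraries and not the make-up of RNA in the cells.

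The targeted genes were examined first. In the hns mutant libraries hns transcripts stood at 17.8%, 20.4%, 21.8% and 34.04% of the wild-type level at 60, 120, 180 and 420 min (128, 155, 271 and 161 ppm). In the fis-labelled libraries fis transcripts were present at 900, 399, 54.7 and 3.23 ppm, which was 80.8%, 67.5%, 28.8% and 42.5% of wild type, the last value from 2 reads against 4. The level of fis therefore does not separate these libraries from wild type at the early times, and they are called fis-labelled throughout. How much of the gene was deleted is not given in the labels, so reads outside a deleted part check nothing. The gene upstream in the same operon, dusB (a tRNA-modifying enzyme, named after its values were seen), was 3.43-fold, 3.82-fold, 1.62-fold and 6.49-fold of wild type in the fis-labelled libraries. The ratio of fis to dusB was 0.368, 0.249, 0.265 and 0.0505 there, and between 0.696 and 1.56 in the other 9 libraries. In wild type fis itself was at 1114 ppm at 60 min and 7.61 ppm (4 reads) at 420 min, a log2 difference of −7.04 as deposited and −5.67 after median-of-ratios scaling. The hns transcript was at 722 ppm at 60 min and 472 ppm at 420 min, which is −0.61 as deposited but 0.85 after that scaling.

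**Figure D1:**
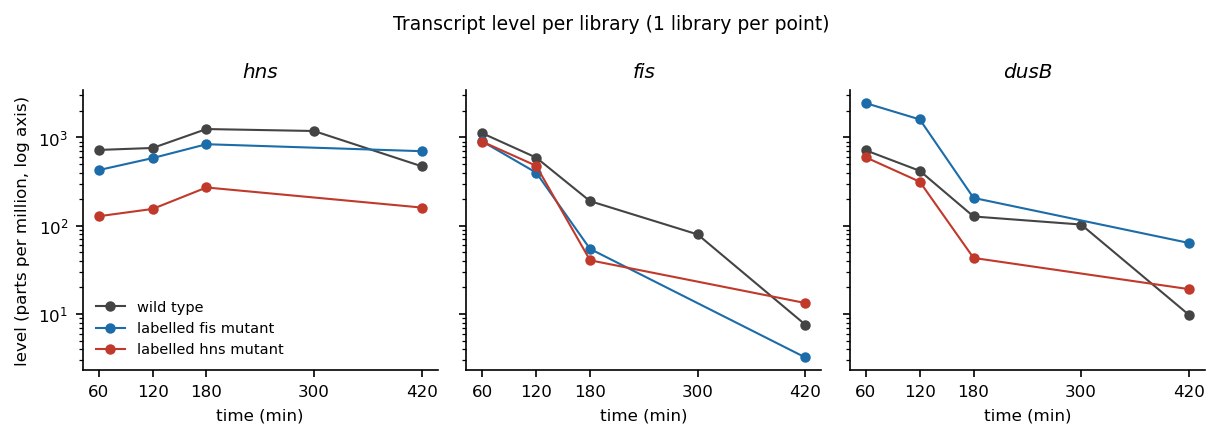
Levels of hns, fis and dusB (ppm, log axis) against time in minutes, with 1 point per library and lines joining libraries of 1 genotype label. In the hns mutant hns lies between 128 and 271 ppm, below all wild-type values, whereas fis in the fis-labelled libraries lies close to wild type at 60 min (900 against 1114 ppm).

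The first comparison asked which genes differ between 60 and 420 min in wild type; the labels give the minutes and no growth phase. At 420 min all 54 ribosomal protein genes and all 11 translation factor genes were at least 2-fold lower than at 60 min, while 26 of 28 stationary phase genes dependent on RpoS, the general stress sigma factor, were at least 2-fold higher. Genes for acid resistance (12 of 15) and for the use of acetate through the glyoxylate shunt (6 of 6) were also higher. Among single genes, rmf, which encodes the factor that pairs ribosomes into inactive dimers, was 1117-fold higher (57.4 and 64098 ppm, interval 815 to 1541), and dps, encoding a DNA-protecting protein of starved cells, was 115-fold higher (interval 101 to 133). The ribosomal protein gene rplQ was 110-fold lower, at 6686 ppm early and 60.8 ppm late. In all, 621 genes were higher and 2042 lower, but the median gene was lower by a log2 value of −1.36. After median-of-ratios scaling the counts were 1166 and 1217, so the share of higher genes was 23.3% as deposited and 48.9% scaled. List medians for 420 min are therefore given relative to the median of all genes.

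Relative to all genes, the RpoS-dependent list had a median of 6.28 (percentile 100 among random lists), with glaH (707-fold higher, 2 reads at 60 min, interval 195 to 5853), involved in glutarate breakdown, and yjbJ (130-fold) at the top. The lowest members were cbpA and katG, with log2 values of 0.35 and 0.44. The acid resistance list stood at 4.13, led by the glutamate decarboxylase gene gadB (52.3-fold, a near-identical copy of gadA and so uncertain) and slp (41.3-fold), whereas yhiM and mdtF were at −0.72 and −0.36 as deposited but 0.46 and 0.79 scaled. The acetate and glyoxylate list was at 4.77, with aceA (isocitrate lyase) 39.4-fold and aceB (malate synthase) 17.9-fold higher. Genes for sugar and carbon source uptake were at 2.02, with 15 of 33 higher and 4 lower as deposited and 25 and 2 scaled. The glycerol genes glpF (60.6-fold) and glpK (26.05-fold) were the highest of them, and rbsK (10.01-fold) and ptsG (7.17-fold), the main glucose transporter, were the lowest. Tricarboxylic acid cycle genes were at 1.60, with 4 of 15 higher as deposited and 13 scaled. In that list fumC (27.3-fold) and acnA (25.1-fold) were higher and acnB was 2.84-fold lower as deposited, with a log2 value of −0.04 when scaled. The sigma factor list was at 0.75 relative to all genes, yet at −0.61 as deposited, with rpoS 3.49-fold higher and rpoD, the housekeeping factor, 4.85-fold lower.

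On the other side, the ribosomal protein list lay at −3.97 relative to all genes (percentile 0), with rpsU 10.5-fold lower as its least affected member. The translation factors lay at −2.83 (percentile 3.16), where tsf (36.2-fold) and fusA (34.8-fold), both elongation factors, stood lowest. The O-antigen cluster was at −2.64 (percentile 0.06) with 10 of 10 genes lower, including rfbC (42.1-fold, 4 reads at 420 min) and wbbI (31.1-fold). The list of respiratory chain and ATP synthase genes was at −2.05 (percentile 2.74), with 28 of 29 lower as deposited and 23 when scaled. Its ATP synthase gene atpD was 37.4-fold lower. Topoisomerase genes, which set DNA supercoiling, were at −2.01 (percentile 4.7) with all 6 lower, among them parE (31.7-fold) and gyrB (17.02-fold). Nucleotide biosynthesis genes were at −1.48 (percentile 0.08) with 22 of 22 lower as deposited and 16 scaled. The iron uptake list was at −0.96 (percentile 0.99, 18 of 24 lower, 13 scaled), where the ferric citrate genes fecB and fecA were 59.4-fold and 38.7-fold lower. Of 36 amino acid biosynthesis genes 32 were lower as deposited and 14 when scaled, with a median of −0.45 (percentile 10.7). The heat shock list was at −1.21 (14 of 16 lower, 9 scaled), but at percentile 26.6 it was not set apart from random lists of its level.

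Several lists lay close to the median of all genes or depended on the scale. Glycolysis genes were at −0.42, with 8 of 11 lower as deposited and 3 scaled. SOS genes were at −0.05 relative to all genes, −1.41 as deposited and 0.01 after median-of-ratios scaling, with 9 of 14 lower as deposited and 2 scaled. The nucleoid-associated protein genes were at 0.21 relative to all genes but at −1.15 as deposited: dps and ihfA (3.31-fold) were higher, and fis and the H-NS paralogue stpA (24.1-fold, 6 reads at 420 min) were lower. The H-NS silenced loci were at 0.77 relative to all genes but at −0.59 as deposited, and the osmoprotectant transport genes proX (50.2-fold lower) and proV (3 reads at 420 min, 120-fold lower, the ratio 0.00831 having an interval of 0.00171 to 0.0244) stood lowest. Anaerobic respiration and fermentation genes were at 1.55, with focA (3.65-fold) and pflB (3.07-fold) of formate metabolism higher. The flagellar list was at 1.26 relative to all genes but at −0.10 as deposited, or 0.42 with counts of 0 set to the floor. Its values at 420 min rest on few reads, such as 0 reads of the master regulator gene flhD against 10 at 60 min. Ribosomal RNA genes were at 2.87 with 12 of 18 higher; rrsG was 5.68-fold higher and rrlE 28.4-fold lower, but reads cannot be assigned among these copies with certainty.

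The other genes furthest from their 60 min level included bssR, a biofilm regulator, with 2 reads early and 2099 late (2859-fold, interval 690 to 20614), and ychH (619-fold). Genes astC (735-fold) and astA (464-fold) of arginine catabolism were higher, and astE of the same operon had 0 reads at 60 min and was at least 321-fold higher. Also higher were the aldehyde dehydrogenase gene aldB (680-fold), yodD (1 read at 60 min, 690-fold, interval 123 to 27322) and yohC (0 reads at 60 min, at least 418-fold higher). The biotin synthase gene bioB had 1863 reads at 60 min and 0 at 420 min, at least 261-fold lower, and bioF of the same pathway had 2 reads late (294-fold lower, the ratio 0.00341 having an interval of 0.000412 to 0.0123). The gene cspA, for the major cold shock protein, had 1039 reads early and 2 late, apt (purine salvage) 1072 and 1, and plaP (putrescine import) 3142 and 5. The small gene yoeI (at least 22.6-fold lower) and the transfer RNA genes thrV (at least 13.3-fold), leuU (at least 16.6-fold), lysZ (at least 11.3-fold) and argZ (at least 6.06-fold) had 0 reads at 420 min, but short genes with near-identical copies are uncertain.

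The lists differed in timing. At 120 min, when 410 genes were higher and 193 lower than at 60 min (403 and 192 scaled), all 15 tricarboxylic acid cycle genes, 24 of 33 uptake genes and 21 of 26 flagellar genes were at least 2-fold higher, with medians of 3.29, 2.95 and 1.99 relative to all genes. At that time the ribosomal protein list was at −0.14 and the RpoS-dependent list at 0.40. At 180 min (1114 genes higher, 455 lower; 875 and 715 scaled) all 54 ribosomal protein genes were lower, with a median of −2.09, 27 of 28 RpoS-dependent genes were higher, with a median of 2.59, and 21 of 24 iron uptake genes were lower, with a median of −3.16. The tricarboxylic acid cycle list was at its highest then, at 4.53, and the flagellar list at 2.65. At 300 min (1065 higher, 914 lower; 1024 and 963 scaled) the acetate and glyoxylate list stood at 5.31 and the RpoS-dependent list at 4.96. No replicate check exists for any of these differences.

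**Figure D2:**
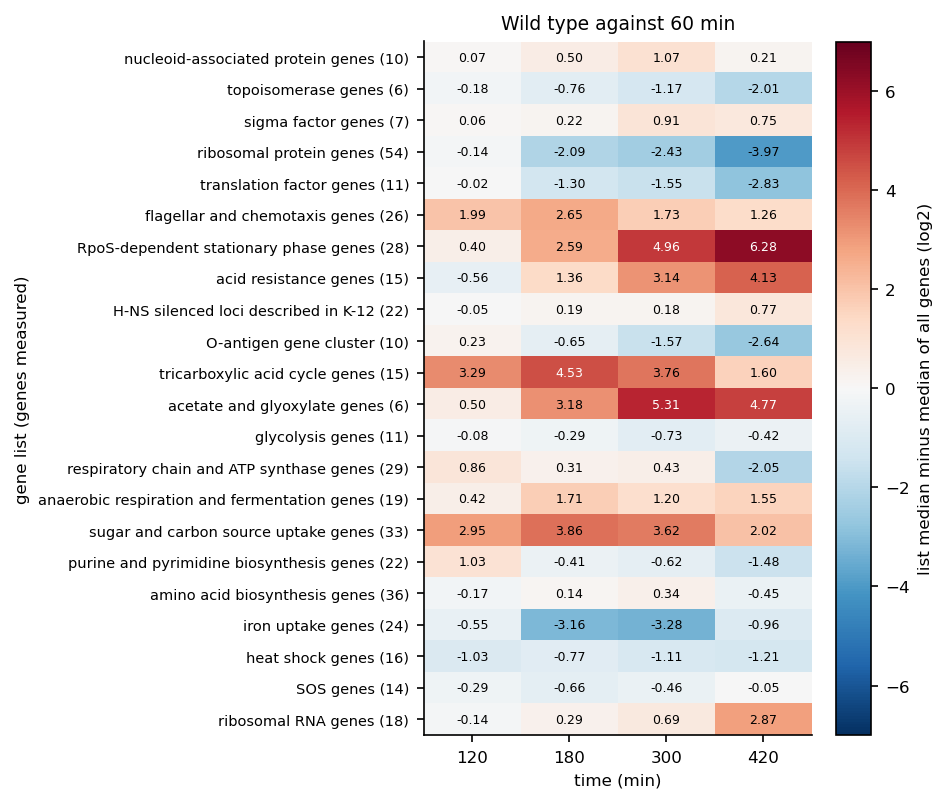
Median log2 difference of each gene list from the 60 min library, minus the median of all genes, in wild type at 120, 180, 300 and 420 min; the number of genes measured stands in brackets. Tricarboxylic acid cycle genes are highest at 180 min (4.53), RpoS-dependent genes are highest at 420 min (6.28) and ribosomal protein genes are lowest at 420 min (−3.97).

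The second comparison asked which genes differ from wild type in the fis-labelled libraries; all directions here rest on that label. Few genes stood apart at all 4 times: 7 were higher and 1 lower, and exchanging the labels within times listed up to 22 genes. The counts depended on each time: they were 25 and 5 without 60 min, 11 and 2 without 120 min, 35 and 3 without 180 min, and 17 and 37 without 420 min, where lower genes became the majority. The largest difference was in ptrA, which encodes protease III, with a mean log2 difference of 2.12 (1.20 to 2.81 over the times; 1751 reads against 272 at 60 min). The neighbouring genes ycgZ and ymgA, for small regulatory proteins, were higher by 1.82 (1.61 to 2.34) and 1.47 (1.11 to 1.79). The acid resistance list had a median of −1.01 (percentile 0), though 0 of its 15 genes passed the rule at all 4 times. Its gene hdeB, for a periplasmic acid chaperone, stood at −1.45 (−2.76 to −0.42).

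The remaining listed genes were ypdK (1.43, under 1 read in both libraries at 420 min), 3 entries that matched no reference gene (ryfb, yghx_1 and yghx_2, named after their values were seen) and, on the lower side, the prepilin peptidase gene pppA (−1.49, 0 reads against 2 at 420 min). Median-of-ratios scaling left 1 higher gene, ypdK, and gave 4 lower genes, pppA, yhiD, hdeB and hdeA, of which the last 3 belong to the acid resistance list. With upper quartile scaling the higher gene was ptrA and the 4 lower genes were those same genes; hdeA was named here after its values were seen. At single times 224 genes were higher and 300 lower at 60 min, 184 and 355 at 120 min, and 284 and 389 at 180 min. At 420 min the counts were 1828 and 129, with a median over all genes of 1.01, and after scaling they were 641 and 511, so the share of higher genes was 93.4% as deposited and 55.6% scaled.

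No member of any list passed the rule at all 4 times on the deposited scale. Relative to all genes the acid resistance list stood at −0.39, −0.52, −1.67 and −1.71 at 60, 120, 180 and 420 min. The RpoS-dependent list stood at −0.15, −0.19, −0.92 and −0.88 (percentile 0 for its mean), with wrbA lowest at a mean of −0.87 and glaH highest at 0.60. The H-NS silenced loci, at −0.62, −0.85, −0.63 and −0.39 (percentile 0), had evgA, a response regulator gene, lowest at −1.06 and ydeP highest at 0.38. The nucleoid-associated protein genes were at −0.45, −0.43, −0.59 and −0.52 (percentile 0.18), with stpA at −0.61. Ribosomal RNA genes were at −0.36, 0.15, −0.14 and −1.83, with rrsA at −1.25. The flagellar list was at −1.29 at 120 min and between −0.27 and 0.11 at the other times, and its chemoreceptor gene aer was higher by a mean of 1.26.

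Iron uptake genes stood on both sides of wild type: their median relative to all genes was −1.17 at 60 min, −2.01 at 120 min, 1.35 at 180 min and 0.15 at 420 min. The outer membrane receptor gene fiu ranged from −3.67 to 1.42 over the times and fecB from −2.17 to 2.30, while feoA, of ferrous iron uptake, ranged from −0.04 to 2.77. Uptake genes for sugars and carbon sources were at −0.72, −0.41, 1.21 and 0.61, with the maltose binding protein gene malE between −0.51 and 4.45 and the ribokinase gene rbsK between −1.05 and 4.87. Heat shock genes were at 1.80 at 180 min and between −0.41 and −0.09 at the other times, with ibpB reaching 3.34 and lon 1.67. The tricarboxylic acid cycle list was at −1.03 at 60 min and 0.80 at 420 min, and the respiratory list at −0.47 and 1.23. Averaged over the times, the lists of topoisomerases, sigma factors, ribosomal proteins, translation factors, O-antigen, tricarboxylic acid cycle, acetate and glyoxylate, glycolysis, respiration, anaerobic metabolism, sugar uptake, amino acid biosynthesis, heat shock and SOS genes all lay between −0.23 and 0.30 relative to all genes, but single times lay further out. At 420 min the O-antigen cluster was at 1.08, ribosomal proteins at 0.91, translation factors at 0.66 and topoisomerases at 0.61, whereas ribosomal proteins were at −0.63 at 180 min (15 of 54 lower), acetate and glyoxylate genes at −0.83 at 120 min and glycolysis genes at −0.67 at 60 min. The purine and pyrimidine list was at −0.12 relative to all genes but at 0.01 after median-of-ratios scaling. In the simulation of this comparison the rule listed 44 of 50 genes changed 4-fold. Folds between the 2-fold threshold and 4-fold were not simulated. The simulated changes were the same at all 4 times, without an offset between libraries. The real library at 420 min had a median over all genes of 1.01. That recovery therefore does not describe this comparison, above all for lower genes.

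The third comparison asked which genes differ from wild type in the hns mutant. All 15 acid resistance genes were at least 2-fold higher at all 4 times, with a median log2 difference of 3.44 (percentile 100), and 15 of 22 loci described as silenced by H-NS were too, with a median of 2.31 (percentile 100). The list held 31 loci, of which 9 fell below the filter on level, a filter that includes the hns mutant libraries; over all 31 loci 17 passed, with a median of 1.98. The largest difference was in flu, encoding the surface adhesin antigen 43, with a mean of 5.90 (5.55 to 6.54; 4738 reads against 49 at 60 min). The glutamate-dependent acid resistance genes gadB, gadA and gadC had means of 5.11, 4.99 and 4.94, gadA and gadB being near-identical and so uncertain as single genes. In all, 162 genes were higher and 3 lower at all 4 times; the lower genes were hns itself (−2.13), ymgA (−1.73) and its neighbour ariR (−1.49), which encodes a regulator of acid resistance.

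**Figure D3:**
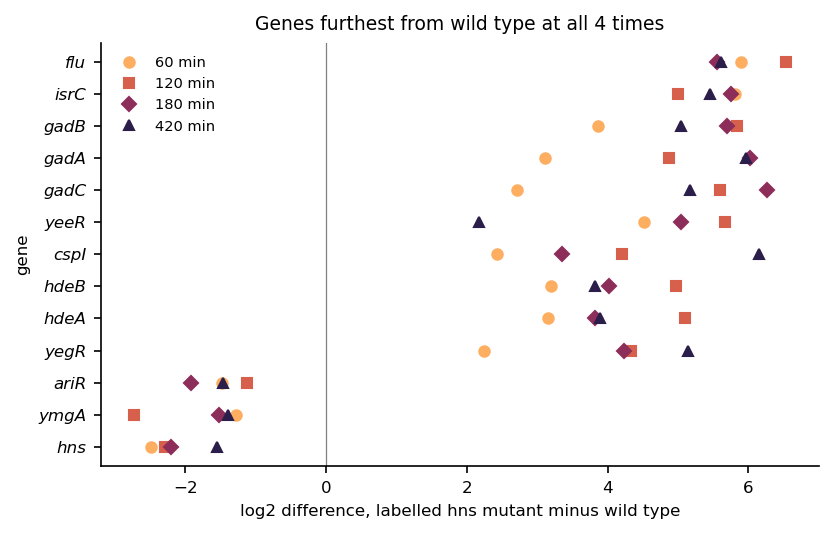
Log2 difference between the hns mutant and wild type for the listed genes furthest from wild type, with 1 point per time. The mean for flu is 5.90 and that for hns −2.13. The listing rule itself places every point of the 10 higher genes at 1 or above.

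Other genes far above wild type were yeeR (4.35), next to flu, the cold shock family gene cspI (4.03), the acid chaperone genes hdeB (4.004) and hdeA (3.994), and yegR (3.989). The small RNA gene isrC (5.50) had 0 reads in wild type at 60 and 420 min, where it was at least 12.6-fold and at least 4.13-fold higher. Single wild-type reads also underlie cspI and yegR. In the acid resistance list the lowest members were the regulator genes gadW (2.28) and gadX (2.56). Relative to all genes its median was 2.66, 3.82, 3.83 and 3.74 at 60, 120, 180 and 420 min, and that of the H-NS silenced loci was 1.72, 2.14, 2.96 and 2.67. In the latter list stpA (3.43) and leuO (3.16), both transcriptional regulators, were highest, and bglJ (0.22) and evgA (1.06) lowest. With median-of-ratios scaling 14 genes of each of these 2 lists passed. Counts at single times were 333 higher and 34 lower at 60 min, 440 and 82 at 120 min, 480 and 256 at 180 min, and 622 and 362 at 420 min. The higher share was 84.3% as deposited and 75.9% scaled at 120 min, and 63.2% and 53.7% at 420 min (597 higher and 515 lower scaled).

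Lists of other functions lay closer to wild type. Of the RpoS-dependent genes 2 of 28 passed, osmB (2.43) and osmC (1.84), both induced by osmotic stress, and the list median relative to all genes was 0.18. It was 0.18, 0.18 and 0.51 at 60, 120 and 180 min, but at 420 min the list was at −0.22 as deposited. The genes cydA (1.42) and cydB (1.48) of cytochrome bd oxidase passed as deposited, but 0 respiratory genes passed when scaled. The nucleoid-associated protein list was at 0.31, with stpA higher and hns lower at all 4 times and dps at a mean of 0.92. None of 26 flagellar genes passed, nor did any of the 26 others that the filter left out. Their median over the times was −0.67 as deposited (percentile 0) and −0.70 relative to all genes, with values of 0.10, −0.70, −1.93 and −0.14 at 60, 120, 180 and 420 min. At 180 min 19 of them were at least 2-fold lower, and the flagellar sigma factor gene fliA had 8 reads against 97. Iron uptake genes stood at −0.78 relative to all genes (percentile 0), and at −0.38, −0.86, −0.27 and −1.81 at the 4 times, with the enterobactin genes entB and entF at means of −1.76 and −1.62 but feoA at 0.89. Ribosomal protein genes were at −0.34 (percentile 0) over the times, but at −0.28, −0.31, −0.996 and 0.28 at 60, 120, 180 and 420 min. Nucleotide biosynthesis genes were at −0.31 (percentile 0.03), with −0.87 at 180 min and −0.19 to −0.11 at the other times, and pyrE was lowest at −1.07. SOS genes were at 0.39 (percentile 99.7), with −0.07, 0.07, 0.52 and 0.77 at the 4 times and recN at 0.88. At 420 min the heat shock list was at 1.25, with groS and groL reaching 2.82 and 2.51, and the O-antigen cluster at 1.17. The lists of topoisomerases, sigma factors, translation factors, O-antigen, tricarboxylic acid cycle, glycolysis, respiration, anaerobic metabolism, sugar uptake, amino acid biosynthesis, heat shock and ribosomal RNA genes all lay between −0.21 and 0.29 over the times, though translation factors were at −0.57 and amino acid biosynthesis genes at 0.59 at 180 min, and ribosomal RNA genes at −0.75 at 420 min. The acetate and glyoxylate list was at 0.10 relative to all genes but at −0.03 after median-of-ratios scaling, and at 0.78 at 180 min.

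**Figure D4:**
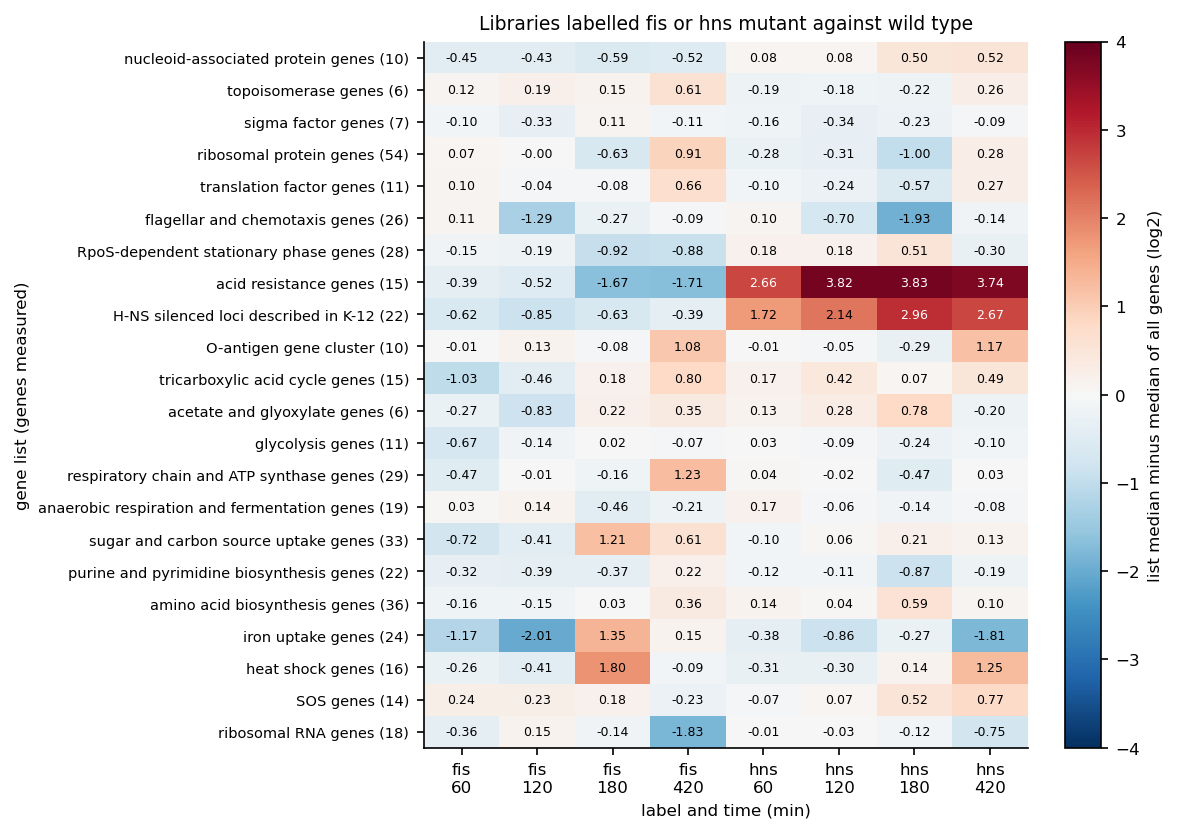
Median log2 difference of each gene list from wild type at the same time, minus the median of all genes, for the fis-labelled and hns mutant libraries at 60, 120, 180 and 420 min. In the hns mutant the acid resistance list lies between 2.66 and 3.83, and in the fis-labelled libraries between −1.71 and −0.39.

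The listed genes of the fis-labelled and hns mutant libraries shared 1 entry. This was ryfb, higher in both (independent lists would share 0.312 genes), and none was lower in both. The biofilm-related gene ymgA was higher in the fis-labelled libraries and lower in the hns mutant. Across genes, which are not independent replicates, the mean log2 differences had a Pearson r of −0.05. Simulated unchanged mutants sharing the wild-type libraries gave 0.46. Those draws carry counting noise only, so their r is not the value that shared wild-type libraries would give among real differences. The covariance was −0.0186 against a simulated 0.0285. With the wild-type times split so that no library served both comparisons, r lay between −0.22 and −0.08. Each list then rested on 2 times, and 3 to 13 genes were higher in both, more than independent lists would share in 5 of the 6 splits (for example 13 against 8.199, and 5 against 8.13 in the remaining split).

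The position of genes on the chromosome was compared with their difference between 420 and 60 min. The row order of the deposited tables was taken as the gene order, with the replication origin placed at mioC. In wild type the 967 genes nearest to the replication origin had a median log2 difference of −1.74 and the 893 farthest genes −0.61, and Spearman's rho across genes was 0.179. Of 10000 rotations of the gene order 2.12% gave a rho as far from 0. The rho was 0.131 (0.35% of rotations) in the fis-labelled libraries and 0.173 (3.21%) in the hns mutant. At 120, 180 and 300 min wild type gave 0.0823 (47.2%), 0.143 (10.3%) and 0.169 (3.4%). For the difference from wild type it was −0.0357 (19.8% of rotations) in the fis-labelled libraries and 0.130 (8.46%) in the hns mutant. For 420 against 60 min the limits of the rotated rho were −0.177 and 0.177 in wild type, and −0.130 and 0.130 in the fis-labelled libraries. They lay close to the rho itself, so a smaller share of rotations does not mean a stronger gradient. Genes are not independent replicates, and the order of genes in CSH50 was not examined.

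**Figure D5:**
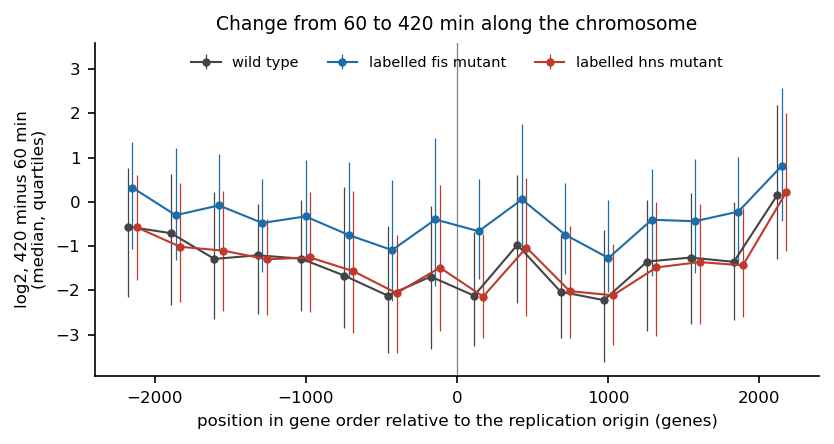
Median log2 difference between 420 and 60 min, with quartiles as bars, for bins of neighbouring genes placed by their position in the gene order relative to the replication origin, for each genotype label. In wild type the 967 nearest genes have a median of −1.74 and the 893 farthest −0.61.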

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

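The tests that exchange genotype labels within times were chosen only after the result was seen. Expressed relative to all genes, 3 lists lay on opposite sides of wild type in the fis-labelled and hns mutant libraries at all 4 times, and the difference itself was not tested because each label and time had 1 library. Acid resistance genes lay between −1.71 and −0.39 in the fis-labelled libraries and between 2.66 and 3.83 in the hns mutant, a difference of 4.58 between the means. The H-NS silenced loci lay between −0.85 and −0.39 and between 1.72 and 2.96, a difference of 2.995. The nucleoid-associated protein genes lay between −0.59 and −0.43 and between 0.08 and 0.52, a difference of 0.791. This list holds fis and hns themselves, and it shares stpA with the H-NS silenced loci, so these lists are not separate. As deposited, the fis-labelled library at 420 min lay above wild type for both, at 0.49 for nucleoid-associated proteins and 0.62 for H-NS silenced loci.

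Genotype labels were exchanged within times in the 8 possible ways, counting the real labels. For the hns mutant the real labels listed 165 genes and the highest other split 2, and 1 of 8 splits listed as many as the real one. For the fis-labelled libraries the real labels listed 8 genes and the highest other split 22, and 3 of 8 splits listed as many. With 8 splits no share under 0.05 can be reached.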

How the results depend on the processing

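The minimum of 20 reads, the pairing of the fis-labelled library at 420 min with wild type at 300 min, median-of-ratios scaling without 420 min, and the rule by which list medians were labelled were chosen only after the results were seen. The main counts (higher and lower) were 621 and 2042 in wild type, 7 and 1 in the fis-labelled libraries, and 162 and 3 in the hns mutant. A 10-fold lower pseudocount, no filter and the mean of neighbouring columns kept all 6 counts within 1.5-fold. With 5 times the pseudocount there were 0 lower genes in the fis-labelled libraries and 101 higher in the hns mutant, and with the lowest 40% of genes left out 0 and 105, since fewer genes of low level could pass. Median-of-ratios scaling gave 1166 and 1217 in wild type, 1 and 4 in the fis-labelled libraries and 5 lower in the hns mutant. Upper quartile scaling gave 1088 and 1313 in wild type and 1 and 4 in the fis-labelled libraries; both scalings remove the offset of the late libraries. A 4-fold threshold gave 385 higher in wild type, 0 and 0 in the fis-labelled libraries and 43 and 0 in the hns mutant; a 1.5-fold threshold gave 34 and 6, and 278 and 10. At least 20 reads on average left 3 higher in the fis-labelled libraries and 103 in the hns mutant.

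Leaving out each time in turn gave 11 to 35 higher and 2 to 37 lower genes in the fis-labelled libraries, the 37 without 420 min and the 35 without 180 min, and 175 to 234 and 3 to 10 in the hns mutant, the 10 without 60 min and 5 without 420 min. Median-of-ratios scaling without 420 min gave 17 and 29 in the fis-labelled libraries, and wild type at 300 min beside their 420 min library gave 17 lower. In wild type 180 min as the early library gave 261 higher, and 300 min as the late library gave 1065 and 914. The cause of these shifts was not tested.

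A list median was taken to have moved when it shifted by more than 1.5-fold. It was taken to have reversed when its sign changed and its main value was at least 0.5 from 0, so sign changes of smaller medians were not counted. The rule replaced an earlier one based on the spread of single genes, which does not describe the spread of a median; without replicates neither measures it. With 5 times the pseudocount 66 of 69 medians stayed, and those that moved were acetate and glyoxylate (2.37) and purines and pyrimidines (−1.76) in wild type and the H-NS silenced loci in the hns mutant (1.72). Median-of-ratios scaling left 46 medians, moved 19 and reversed 4, all in wild type at 420 min, whose offset it removes. The reversed medians were nucleoid-associated proteins 0.31, sigma factors 0.84, H-NS silenced loci 0.48 and SOS 0.0138. The lower ones became topoisomerases −1.94, ribosomal proteins −3.88, translation factors −2.77, O-antigen −2.65, glycolysis −0.33, respiration −1.97, purines and pyrimidines −1.89, amino acids −0.58, iron uptake −1.09, heat shock −1.12 and the pair fis and hns −2.41. The others became flagella 0.81, RpoS-dependent 6.36, acid resistance 4.15, tricarboxylic acid cycle 1.69, acetate and glyoxylate 4.79, anaerobic metabolism 1.38, sugar uptake 1.90 and ribosomal RNA 2.98. Under this scaling the sign was kept by 18, 19 and 22 of 23 lists in the wild-type, fis-labelled and hns comparisons. For the difference from wild type, the rank correlation with gene order in the fis-labelled libraries was −0.0191 with the lowest 40% of genes left out (5.6% of 1000 rotations as far from 0). With no filter it was −0.0411 (42.3%). In the hns mutant these values were 0.172 (4.1%) and 0.107 (11.9%), so the shares of rotations depended on the filter. At 420 min 624 genes had 0 reads in wild type and 627 in the hns mutant, against 299 in the hns mutant at 180 min, with 1.93, 1.72 and 2.02 M reads. The total of reads alone therefore does not account for the zeros in wild type. Stable RNAs took 68.9% of signal in wild type at 420 min and 28.6% in the hns mutant at 180 min. The median gene was at 5.95 and 25.1 ppm there, so fewer reads for other genes may account for the zeros.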

Other observations

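The gene groups in the first paragraph and all tests in this part were chosen only after the results were seen, except the test that left out gene lists. Several operons outside the lists stood apart at single times; their medians are given relative to all genes. In wild type the ast operon for arginine catabolism was at 5.70, 8.69 and 9.29 at 180, 300 and 420 min against 60 min, and the biotin biosynthesis genes were at −5.61, −4.71 and −5.66. In the fis-labelled libraries the oligopeptide permease operon was at −1.95, −1.12, −1.69 and 1.999 at 60, 120, 180 and 420 min, and the glycine cleavage operon at −1.90, −2.97, −0.96 and 0.42, so both stood on the other side at 420 min. They were also higher in the hns mutant against the same wild-type library at 420 min (1.54 and 1.10). Other groups changed sides in the fis-labelled libraries between 180 and 420 min. The dipeptide permease operon was at −2.05 and 3.74, the ferric citrate genes (partly in the iron uptake list) at −0.98 and 1.29, and the type 1 fimbrial genes at −0.95 and 1.21. In the hns mutant at 420 min these groups were at 0.11, −0.04 and 1.76. At 180 min in the fis-labelled library the biotin genes were at 4.57, the galactarate and glucarate genes at 3.10 and the nrdHIEF operon for ribonucleotide reduction at 2.8996. Against the same wild-type library the hns mutant had 2.87, 0.92 and −0.29 for these 3 groups. In the hns mutant the type 1 fimbrial genes were at 1.995, 1.20, 1.02 and 1.76 (7, 7, 5 and 6 of 7 at least 2-fold higher) and the arn operon, which modifies lipid A, at 1.27, 1.37, 2.499 and 2.34 over the 4 times. Members of the arn operon went both ways: 3, 3, 4 and 4 of the 6 measured were at least 2-fold higher, and 1 was at least 2-fold lower at 180 and at 420 min. The lac-pro region, which CSH50 is described as lacking, gave 0 reads for lacZ, lacY, lacA and lacI in all 13 libraries, and at most 3 reads for proA and 1 read for proB in any library.

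At 420 min the fis-labelled library differed from wild type by at least 2-fold in 1957 genes, far more than at other times. A few abundant RNAs taking most of the reads cannot be the whole cause, since 1152 genes remained apart after median-of-ratios scaling, against at most 637 at the other times. Nor can low depth, since among 594 genes with at least 50 reads in each of the 8 libraries compared 24.9% were apart at 420 min and at most 12.8% at other times. The same library was closer to wild type at 300 min, with 498 genes apart on the same scale, so an earlier place on the wild-type time course may account for part of the pattern. Whether that would come from the genotype or from sampling could not be tested with 1 culture, and the hns mutant at 420 min was 1112 genes apart from wild type at 420 min and 1565 from wild type at 300 min. At 60, 120 and 180 min the hns mutant was 308, 449 and 729 genes apart on that scale. A higher count against the wild-type library at 420 min was therefore not particular to the fis-labelled library.

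The presence of fis transcripts in the fis-labelled libraries was set against 2 technical explanations. Wild-type RNA mixed into the libraries at 60 and 120 min, if like the wild-type library of that time, would hold every gene at or above the fis ratio. That ratio was 80.8% and 67.5%, but 17 of 24 iron uptake genes were below it at both times, with medians of 44.6% and 24.02% of wild type. At 180 and 420 min, where the fis ratio was 28.8% and 42.5%, 0 of 24 were below it, so these genes do not decide about mixing at those times. Wild-type libraries carrying a wrong label would have a ratio of fis to dusB like that of the other libraries of the same time. The counting intervals lay apart from those of both wild type and the hns mutant in 3 of 3 libraries at 60, 120 and 180 min. These intervals hold no variation between cultures. The ratio itself was at most 0.368 in the fis-labelled libraries, against 0.696 to 1.56 over all wild-type and hns mutant libraries, which argues against a wrong label at those 3 times. At 420 min the interval of 0.00701 to 0.217 (2 fis reads) overlapped that of wild type (4 reads, 0.187 to 2.35), so 0 of 1 library lay apart and a wrong label of that library stays open on this measure. The interval did lie apart from those of the hns mutant at 420 min (0.253 to 1.86) and wild type at 300 min (0.579 to 1.004), and dusB was 6.49-fold of wild type (111 against 17 reads). A partial deletion or insertion that leaves part of fis transcribed may remain as a hypothesis; coverage along the gene was not analysed here.

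In wild type, genes near the replication origin had a more negative log2 difference between 420 and 60 min than genes far from it. The median difference of the 893 farthest genes exceeded that of the 967 nearest by 1.12. This gap was 0.977 over 3498 genes without the lists of ribosomal proteins, translation factors, respiration, purines and pyrimidines and ribosomal RNA, which argues against these lists as the whole cause. Among 658 genes with at least 50 reads in both libraries it was 1.04, which argues against low depth as the whole cause. A higher gene copy number near the origin in replicating cells at 60 min is a candidate explanation that stays open, since no DNA was measured.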
